A study of Mus musculus with 16 samples.

How the data were processed

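The right cortical mantle of 16 mice was flash frozen and its nuclei were released by homogenisation and captured with the 10x Chromium chemistry for 3' ends, per the labels' protocols. Each library came from 1 mouse. Of the 16 titles, 15 give a distinct animal number and 1 none, so libraries were treated as separate animals. Replicate numbers, given in accession order, pair no samples. The labels give neither the sex of the mice nor a batch within an age. The younger and older mice were sequenced under different run codes.

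The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. Per the submitters' processing notes they were made with Cell Ranger 3.1.0 against GRCm38, and settings beyond these names were not given in the sources used here. The human APOE coding sequence has a feature of its own in the matrices. Gene positions were taken from an annotation of GRCm38, which matched 31023 of 31125 features.

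Barcodes were kept with at least 500 UMIs and 300 genes and at most 5% mitochondrial UMIs. Doublets were scored by simulated-doublet neighbours, and the highest scores in each library were removed at a rate of 0.8% per 1000 barcodes deposited, or 6.70% to 12.0% of barcodes. Nuclei of all libraries were clustered together on 2000 variable genes, with log values centred within each library, 40 principal components, 20 nearest neighbours and Leiden clustering at a resolution of 1.0. Vascular nuclei were clustered again. A cluster took the name of a class when at least 4 markers fixed before the data were examined were at least 2-fold higher there and found in a share of at least 0.2 of its nuclei, with more than 1.5 times as many such markers as the next class. These limits, unlike the markers, were set after the data were examined. Class names therefore stand for clusters like the named type, such as endothelial-like. Clusters in which a share over 0.4 of nuclei had doublet scores past the limit, whose leading genes held more markers of another class, or whose nuclei were shallow and lacked leading markers, stayed unnamed. They held 9.70 ± 2.47% and 9.77 ± 1.41% of kept nuclei in the younger E3 and E4 groups and 10.1 ± 1.19% and 9.90 ± 1.16% in the older ones (SD over libraries).

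Counts were summed per library and class, leaving out a class in a library with under 10 nuclei, which removed the 4 pericytes of E3_2-3m_r4. E4 and E3 mice were compared within each age, the effects between ages, and the ages with genotypes averaged. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, the filterByExpr filter and 1 fit over all 4 groups. Adjusted p are Benjamini-Hochberg values over all genes tested in a class, with a threshold of 0.05. Standard errors of log2 folds were computed as the fold over the square root of the F statistic. Gene lists, 40 in number and fixed before the data were examined, and the markers of the other classes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation between genes of 0.01 and again with an estimated correlation. Lists with fewer than 3 tested members were left out, and camera adjusted p are Benjamini-Hochberg values over the lists of a class and age. Shares of nuclei were compared by two-sided exact permutation tests, adjusted over classes and ages.

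Genes named in the text were chosen by a rule fixed before the data were examined. At each age and class it takes the 5 smallest adjusted p in each direction among called genes, with at most 30 genes per age and at least 2 per class with calls. Sex-linked genes were left out of it and are reported once. With no call in endothelial nuclei, pericytes, excitatory neurons or microglia, the gene of smallest p is given as not passing. Up to 4 members of smallest p stand for each passing list, and APOE, Cldn5, Slc2a1, Pdgfrb and Lrp1 are taken in every class. Predicted genes are named only where called in at least 2 classes.

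The edgeR and camera steps and the correction for GC content were tested on simulated data, in which 200 genes were changed by known folds. In excitatory neurons at 2–3 months, on 19184 genes, 37 of 67 genes changed 1.5-fold were found, 49 of 67 changed 2-fold and 63 of 66 changed 4-fold. Pairs of replicates differed by more than sampling noise, with chi-square per degree of freedom from 11.6 to 79.2. Alternatives fixed before the data were examined were DESeq2 1.42.0, relative log expression factors, no low-count filter, only the libraries of 1 age, no doublet removal, a stricter filter at 1000 UMIs and 1% mitochondrial UMIs, Xist as a covariate, at most 50 nuclei per class and library, edgeR on numbers of nuclei for shares, APOE over all kept nuclei, and each library left out in turn. Corrections for GC content and gene length, with trends fitted per library by lowess at a span of 0.3, draws of equal numbers of excitatory nuclei or like shares of their clusters, inhibitory neurons without cluster 28, passing lists with each library left out in turn, and an estimated correlation for lists that differ between ages were added after the results were seen. Clustering used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, sklearn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2.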

Results

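Single nuclei of the right cortical mantle, with hippocampus and visible white matter dissected away, were profiled by droplet-based RNA sequencing in knock-in mice that carry a human APOE coding region flanked by loxP sites. The mice carried either the APOE3 form (E3) or the APOE4 form (E4), the latter being the main common genetic risk factor for late-onset Alzheimer's disease. The series holds 4 E3 and 4 E4 mice at 2–3 months and 3 E3 and 5 E4 mice at 9–12 months, with 1 library per mouse. Libraries are named by group and replicate, so that E4_9-12m_r3 is replicate 3 of the E4 mice at 9–12 months, and a bare r4 after it is replicate 4 of the same group. The deposited tables gave 175552 barcodes, of which 158745 were kept as nuclei. Total counts per library were 48905571 to 75591044 unique molecular identifiers (UMIs) at 2–3 months and 76630849 to 114598981 at 9–12 months. The median kept nucleus held 3772.5 to 4141 UMIs in the younger and 7000 to 8856 in the older libraries. The series title asks whether APOE4 acts on cells of the blood vessels before it acts on neurons and synapses.

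The knock-in gene was counted as human APOE (ENSG00000130203), whose product carries lipids between brain cells, while mouse Apoe was not analysed here. Levels are given as CPM, the UMIs of a gene scaled to the summed counts of its class and library. Astrocytes held 1184 ± 348 APOE CPM in E3 and 1110 ± 417 in E4 mice at 2–3 months (SD, n = 4 each), and 1007 ± 228 (n = 3) and 887 ± 166 (n = 5) at 9–12 months. The log2 fold of E4 over E3 in astrocytes was −0.10 ± 0.21 (SE) in the younger and −0.11 ± 0.21 in the older mice. Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.948 and 0.99995). At least 1 APOE UMI was found in 71.9% and 71.1% of E3 and E4 astrocytes at 2–3 months and in 87.1% and 84.1% at 9–12 months, at medians of 1444 to 3635 UMIs per nucleus. Excitatory neurons, which were deeper at medians of 5144 to 11110 UMIs, had such a UMI in 15.4% and 18.4% of nuclei at 2–3 months and 27.3% and 28.2% at 9–12 months. Endothelial nuclei held 852 ± 119 and 880 ± 134 APOE CPM in the younger and 614 ± 98.4 and 605 ± 57.9 in the older E3 and E4 mice. The count does not tell the APOE3 form from the APOE4 form, so it does not check the genotype labels.

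The makeup of the cortex was compared first. Excitatory neurons were the most common class, at 49.9 ± 3.46% of kept nuclei in E3 and 48.7 ± 2.05% in E4 mice at 2–3 months and 43.7 ± 2.30% and 46.3 ± 5.19% at 9–12 months (SD, n = 4, 4, 3 and 5). Endothelial nuclei, which line the vessels, made up 0.497 ± 0.0587% and 0.535 ± 0.165% at 2–3 months and 1.05 ± 0.188% and 1.20 ± 0.365% at 9–12 months. Pericytes, the contractile cells wrapped around capillaries, made up 0.132 ± 0.0862% and 0.206 ± 0.0812% in the younger and 0.651 ± 0.111% and 0.952 ± 0.350% in the older E3 and E4 mice. The pericyte to endothelial ratio was 0.267 ± 0.164 and 0.434 ± 0.267 at 2–3 months (p = 0.343, two-sided exact permutation test) and 0.623 ± 0.0482 and 0.868 ± 0.439 at 9–12 months (p = 0.411). Vascular fibroblasts had the only share to reach the smallest p that 4 against 4 mice allow, at 0.508 ± 0.140% in E3 and 0.763 ± 0.0479% in E4 mice at 2–3 months (p = 0.0286, exact permutation test, two-sided). It did not pass adjustment over the 22 comparisons of shares (Benjamini-Hochberg adjusted p = 0.589), and at the older age it was 0.773% in both genotypes. Astrocytes made up 4.51 ± 0.795% and 6.03 ± 1.03% at 2–3 months (p = 0.0857, exact permutation test) and striatal-type neurons 9.91 ± 1.76% and 6.60 ± 2.67% at 9–12 months (p = 0.125, where the smallest possible is 0.0179). The striatal-type difference, E4 minus E3, was −3.31 percentage points and −2.20 without E4_9-12m_r5, which held 2.13%. No share passed after adjustment, with adjusted p from 0.589 to 1 over classes and ages.

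**Figure D1:**
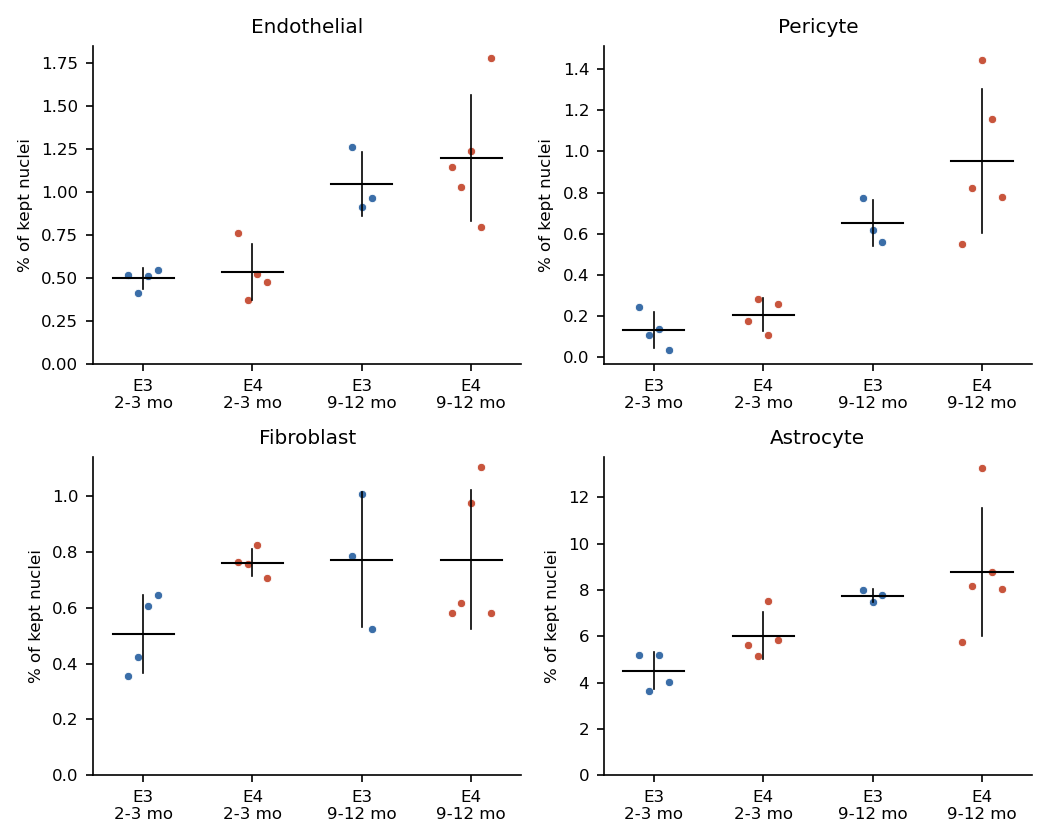
Percent of kept nuclei (vertical axis) per library in endothelial nuclei, pericytes, fibroblasts and astrocytes of each group; points are libraries, lines group means and bars ± 1 SD. The fibroblast means at 2–3 months are 0.508% in E3 and 0.763% in E4 mice.

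At 2–3 months 424 of 19537 tested genes passed the threshold in excitatory neurons, the class with the most nuclei, with 216 higher and 208 lower in E4 mice. Angpt1 (ENSMUSG00000022309, angiopoietin 1, a ligand of the endothelial receptor Tie2; GRCm38 chromosome 15, 42424723 to 42676977, minus strand) rose from 18.1 ± 3.64 to 35.3 ± 1.66 CPM, a log2 fold of 1.05 ± 0.12 (SE; edgeR adjusted p = 0.00149). Epha3, a receptor of axon guidance (chromosome 16, 63543534 to 63864175), rose from 104 ± 6.72 to 145 ± 5.55 CPM (0.56 ± 0.07, edgeR adjusted p = 0.00486). Sh3bgrl2 and Cbr4 also rose, by 0.55 ± 0.08 and 0.73 ± 0.12. Cacng2, which encodes stargazin, an auxiliary subunit of AMPA-type glutamate receptors (chromosome 15, 77991748 to 78120028), fell by 0.58 ± 0.09 on the log2 scale from 127 ± 9.71 to 81.1 ± 6.00 CPM (edgeR adjusted p = 0.0163). Sulf2, a sulfatase that edits heparan sulfate, fell by 0.59 ± 0.09, Sema4d, a semaphorin of axon guidance, fell by 0.42 ± 0.07, and Nxn and Nol4l fell by 0.75 ± 0.12 and 0.64 ± 0.11. Lrp1, an endocytic receptor for apolipoprotein E (chromosome 10, 127538161 to 127621148), fell by 0.43 ± 0.10 from 86.1 ± 3.43 to 61.1 ± 5.93 CPM (edgeR adjusted p = 0.0329). The called genes that were higher had a median GC content of 44.8% and those that were lower 55.0%, against 48.7% over all tested genes. With a GC trend removed per library 213 genes were called, 198 of them among the 424. The 424 all kept their direction, their median log2 fold in that direction went from 0.56 to 0.49, and Lrp1 lost its call (−0.29, edgeR adjusted p = 0.0670). Angpt1 and Epha3 stayed past the threshold with any 1 younger library left out. Sh3bgrl2 lost its call without E4_2-3m_r3 and the others named here without that library, E3_2-3m_r2 or E4_2-3m_r4. Cbr4, Nol4l and Lrp1 also lost theirs without E3_2-3m_r3, Nxn and Lrp1 without E3_2-3m_r1 and Lrp1 without E4_2-3m_r1 (edgeR adjusted p up to 0.119). The count went from 424 to 2, 4, 8, 14, 16 and 55 without E4_2-3m_r3, E3_2-3m_r2, E4_2-3m_r4, E3_2-3m_r3, r1 and E4_2-3m_r1. The count was 1089 with DESeq2, 1237 with the younger libraries alone, 1051 with Xist as a covariate and 3 with at most 50 nuclei per library. In this last setting all 25 called values of named genes at 2–3 months that it tested lost their calls, Angpt1 (1.08, edgeR adjusted p = 0.510) and Epha3 (0.47, 0.603) among them. Correction for gene length gave 238 higher and 396 lower.

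Loxl2 (ENSMUSG00000034205, a lysyl oxidase that crosslinks matrix proteins; chromosome 14, 69609068 to 69695834, plus strand) was near 0 in E3 mice and present in E4 mice in 6 classes at 2–3 months. Excitatory neurons held 54 Loxl2 UMIs over the 4 E3 libraries and 7748 over the 4 E4 libraries, or 0.449 ± 0.128 and 55.3 ± 25.3 CPM (edgeR adjusted p = 0.0192). The counts were 7 and 1424 in striatal-type neurons, 21 and 1011 in inhibitory neurons, 1 and 156 in oligodendrocyte precursors, 3 and 63 in oligodendrocytes and 0 and 205 in microglia, all past the threshold by edgeR with adjusted p from 0.00377 to 0.0321. The call was lost in microglia with DESeq2 (adjusted p = 0.213) and the stricter nuclei filter (edgeR adjusted p = 0.503) and in inhibitory neurons with no doublet removal (edgeR adjusted p = 0.0593). With at most 50 nuclei per library it was lost in microglia, excitatory, inhibitory and striatal-type neurons (edgeR adjusted p from 0.0608 to 0.162). DESeq2 gave no adjusted p for it in oligodendrocytes and their precursors. With 1 library left out it stayed in microglia. It was lost in striatal-type neurons without E3_2-3m_r3, in excitatory neurons without E3_2-3m_r1 to r3 or E4_2-3m_r3, in precursors without E3_2-3m_r1 to r3 or E4_2-3m_r1, in oligodendrocytes without these or E4_2-3m_r2 and in inhibitory neurons without any but E4_2-3m_r2 (edgeR adjusted p up to 0.218). At 9–12 months 3 of the 5 E4 libraries held 20.2 to 30.9 Loxl2 CPM in excitatory neurons. The others, E4_9-12m_r3 and r5, held 0.371 and 0.329, within the 0.24 to 0.64 of the E3 libraries. The predicted gene Gm16867, which lies within 1 Mb of Loxl2 on chromosome 14, was called in excitatory and striatal-type neurons at 2–3 months and not at 9–12 months. At the older age it followed Loxl2, at 8.4 to 9.0 CPM in those 3 E4 libraries and 0.124 and 0.128 in the others.

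**Figure D2:**
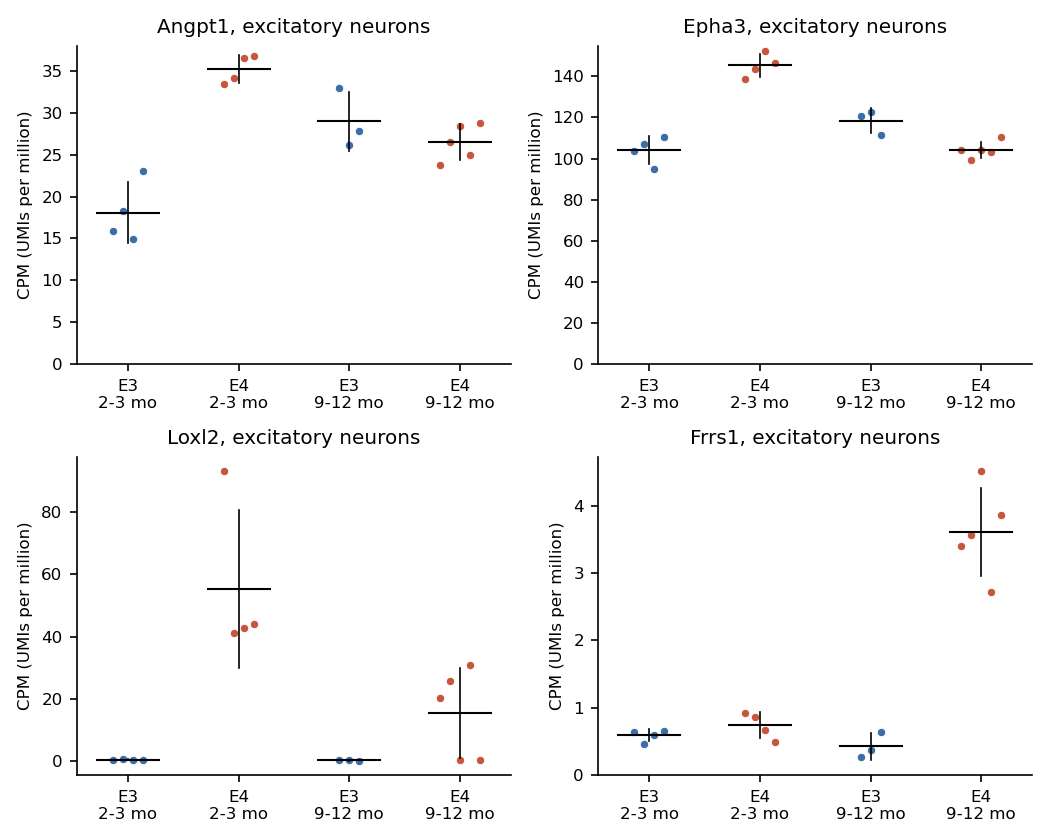
CPM (vertical axis) of Angpt1, Epha3, Loxl2 and Frrs1 in excitatory neurons, per library of each group; points are libraries, lines group means and bars ± 1 SD. Angpt1 averages 18.1 in younger E3 and 35.3 in younger E4 mice against 29.0 and 26.5 in the older mice, and 2 older E4 libraries lie at the E3 level of Loxl2.

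The other classes had few single genes past the threshold at 2–3 months. In oligodendrocytes 6 genes were called, among them Eya4, a transcriptional coactivator, which fell by 2.41 ± 0.42 on the log2 scale from 25.3 ± 3.34 to 4.91 ± 2.46 CPM (edgeR adjusted p = 0.0300), Asna1 and the antisense transcript Nkx2-2os, which were higher. In oligodendrocyte precursors the cytochrome P450 gene Cyp2j8 rose from 3.17 ± 3.56 to 19.7 ± 3.75 CPM (edgeR adjusted p = 0.0262). In inhibitory neurons Arhgef37 fell by 0.75 ± 0.11 (edgeR adjusted p = 0.0321). In striatal-type neurons 4 genes rose, Asna1 and Gab2 among them, and 4 fell, namely Abhd14a, Fkbp2, Cyld and the endoplasmic reticulum chaperone Hsp90b1 (edgeR adjusted p = 0.0394 for each). Nkx2-2os overlaps Nkx2-2 on the opposite strand, so its count is uncertain. With 1 library left out, the 6 oligodendrocyte calls became 0 without E4_2-3m_r1, r2 or E3_2-3m_r3, 1 without E3_2-3m_r2 or E4_2-3m_r4 and 2 without E3_2-3m_r1. The 2 precursor calls became 0 without E3_2-3m_r1, E4_2-3m_r1, E3_2-3m_r2 or r3, 1 without E4_2-3m_r4 and 5 without E3_2-3m_r4. The 2 inhibitory calls became 0 without any library but E4_2-3m_r2, and the 8 striatal-type calls became 0 without E3_2-3m_r3 and 1 without any other but E3_2-3m_r4. DESeq2 called 22, 6, 6 and 42 genes in these 4 classes, among them 4 of the 6, 0 of the 2, 2 of the 2 and 5 of the 8 called by edgeR, and gave no adjusted p for the others, both precursor genes included. The stricter nuclei filter ended the calls of Eya4, Nkx2-2os and Asna1 in oligodendrocytes, relative log expression factors those of Asna1 there and of Cyld and Hsp90b1 in striatal-type neurons, and no doublet removal those of Asna1 in oligodendrocytes and of Arhgef37 (edgeR adjusted p from 0.0504 to 0.152).

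In the vascular classes and microglia at 2–3 months, the genes of the barrier differed by less than their error. Cldn5, the main claudin of endothelial tight junctions, was at 2087 ± 416 and 1827 ± 585 CPM in E3 and E4 endothelial nuclei (log2 fold −0.19 ± 0.25, edgeR adjusted p = 0.922), and Slc2a1, the glucose carrier of the barrier, at 1854 ± 372 and 1565 ± 468 (−0.23 ± 0.24, edgeR adjusted p = 0.915). Pdgfrb, the growth factor receptor that keeps pericytes on vessels, was at 1628 ± 349 and 1532 ± 173 in pericytes (n = 3 and 4). Its fold, fitted with TMM factors, had the opposite sign to these means (0.11 ± 0.27, edgeR adjusted p = 0.987) and was −0.05 with no doublet removal. In microglia Lrp1 was at 280 ± 68.3 and 419 ± 12.0 CPM, a log2 fold of 0.58 ± 0.19 that did not pass (edgeR adjusted p = 0.616). Endothelial nuclei and fibroblasts gave 0 called genes by edgeR, with 274 and 267 at an unadjusted p under 0.05 and 2 and 0 called by DESeq2, and astrocytes gave 0 with 965 and 6. In pericytes the nuclear RNA Malat1 was the only call, at 203610 ± 16594 and 243170 ± 16039 CPM in 3 and 4 libraries (0.41 ± 0.09, edgeR adjusted p = 0.0440). It was lost without E3_2-3m_r1, r2, E4_2-3m_r2, E3_2-3m_r3 or E4_2-3m_r4. It was also lost with no low-count filter, only libraries of that age, no doublet removal (log2 fold 0.21), Xist as a covariate or at most 50 nuclei per library (edgeR adjusted p from 0.143 to 0.883). Astrocytes gave 3 and 1 calls without E4_2-3m_r2 and E3_2-3m_r3. The libraries held 38 to 87 endothelial nuclei and 4 to 34 pericytes at this age. Of simulated changes the test found 16 of 67 genes at 2-fold and 53 of 66 at 4-fold in endothelial nuclei, and 3 and 30 in pericytes. The smallest endothelial p belonged to Trpm3, a cation channel, which was not called (3.49 ± 0.83, edgeR adjusted p = 0.535).

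Of the gene lists fixed before the data were examined, the heat shock and unfolded protein genes, chaperones and folding enzymes of the cytosol and endoplasmic reticulum, were lower in E4 mice in 7 of the 10 classes at 2–3 months. In excitatory neurons all 29 tested members were lower, with a median log2 fold of −0.50 (camera adjusted p = 8.05e-12, and adjusted p = 0.684 with an estimated correlation). Of the 29, 4 fell over all genes tested, Pdia3 by 0.75 ± 0.17, Hsp90b1 by 0.65 ± 0.15, Hspa5, the chaperone BiP, by 0.82 ± 0.21 and the stress transcription factor Xbp1 by 0.56 ± 0.14. These 4 lost their calls without any 1 library but E3_2-3m_r4 or E4_2-3m_r2, and Xbp1 without the latter too (edgeR adjusted p up to 0.156). Hspa5 and Xbp1 also lost theirs with the GC trend removed or like shares of excitatory clusters, and Xbp1 with as many excitatory nuclei per library (edgeR adjusted p from 0.0522 to 0.0628). Of all members 21 were lower adjusted over the list alone. In striatal-type neurons 24 of 26 members were lower (median −0.61, camera adjusted p = 3.21e-18, and adjusted p = 0.271 with an estimated correlation), with 1 called over all genes and 19 adjusted over the list alone. In inhibitory neurons 26 of 28 were lower (−0.40, camera adjusted p = 2.90e-11, and adjusted p = 0.632 with an estimated correlation), 0 over all genes and 14 adjusted over the list alone. The list was lower in 25 of 25 members in oligodendrocytes (−0.48, camera adjusted p = 8.37e-12), 22 of 24 in astrocytes (−0.41, 8.81e-08), 20 of 23 in oligodendrocyte precursors (−0.38, 7.56e-06) and 11 of 12 in fibroblasts (−0.66, 0.00156), with 8, 5, 4 and 1 members adjusted over the list alone. With an estimated correlation these 4 gave adjusted p = 0.393, 0.116, 0.913 and 0.139. Genes of cytoplasmic RNA, a sign of RNA quality in nuclei, were lower beside it in striatal-type neurons (23 of 24 members, −0.29, camera adjusted p = 0.00717), astrocytes (18 of 23, −0.24, 0.0114) and fibroblasts (14 of 16, −0.20, 0.0367), with adjusted p = 0.728, 0.793 and 0.751 with an estimated correlation. They had a median of −0.14 in excitatory neurons without passing (camera adjusted p = 0.0818). Astrocyte markers were higher in the same excitatory and striatal-type neurons (median 0.26 in each) and homeostatic astrocyte genes in the inhibitory neurons (0.17). The heat shock list passed in each of its 7 classes with any 1 younger library left out. The cytoplasmic list lost its call in striatal-type neurons without E3_2-3m_r2, r4 or E4_2-3m_r3, in astrocytes without these or E4_2-3m_r4, and in fibroblasts without any of these or E3_2-3m_r3 (camera adjusted p up to 0.487).

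Genes induced by glucocorticoids were lower in E4 mice in 5 classes at 2–3 months. All 15 tested members were lower in oligodendrocytes (median −0.92, camera adjusted p = 6.97e-06), all 12 in endothelial nuclei (−0.52, 0.0120), all 8 in fibroblasts (−0.68, 0.00864), 14 of 15 in astrocytes (−0.61, 0.00263) and 14 of 16 in excitatory neurons (−0.24, 0.0206). With an estimated correlation these gave adjusted p = 0.831, 0.797, 0.463, 0.774 and 0.684. Members included Zbtb16, a steroid-induced transcription factor, at −2.01 ± 0.61 in oligodendrocytes and −1.65 ± 0.53 in endothelial nuclei, and Tsc22d3, the leucine zipper protein GILZ, at −1.11 ± 0.38 in endothelial nuclei. None was called over all genes. Adjusted over the list alone 5 were lower in oligodendrocytes, 2 in endothelial nuclei and 3 in excitatory neurons, where 1 was higher. Immediate early genes, which neuronal activity and stress induce, were lower in excitatory neurons (26 of 30 members, −0.46, camera adjusted p = 0.00956), endothelial nuclei (12 of 13, −0.50, 0.0120) and oligodendrocytes (11 of 14, −0.22, 0.0279), with adjusted p = 0.684, 0.797 and 0.596 with an estimated correlation. Cholesterol synthesis genes were lower in astrocytes (22 of 24, −0.46, camera adjusted p = 0.000160, and adjusted p = 0.783 with an estimated correlation), where Nsdhl, an enzyme of sterol demethylation, was at −0.80 ± 0.19 and 3 members passed adjusted over the list alone. Cytoplasmic RNA genes were lower in the same astrocytes and fibroblasts (medians −0.24 and −0.20) and had medians of 0.03, −0.11 and −0.14 in oligodendrocytes, endothelial nuclei and excitatory neurons without passing, and astrocyte markers were higher in these excitatory neurons (0.26). With 1 library left out, the glucocorticoid list kept its call in oligodendrocytes. It lost it in astrocytes without E4_2-3m_r2, in endothelial nuclei without E3_2-3m_r2, r3 or E4_2-3m_r2, in fibroblasts without E3_2-3m_r1, E4_2-3m_r2 or r4 and in excitatory neurons without E3_2-3m_r4 or E4_2-3m_r4 (camera adjusted p up to 0.154). The immediate early list lost its call in excitatory neurons without E3_2-3m_r4 or E4_2-3m_r4, in endothelial nuclei without E3_2-3m_r2, r3, r4 or E4_2-3m_r2 and in oligodendrocytes without any library but E3_2-3m_r1, E4_2-3m_r1 or r2 (up to 0.416). The cholesterol list in astrocytes lost it without E3_2-3m_r4 (0.0674).

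Genes of energy supply were also lower in E4 mice at 2–3 months. Nuclear genes of oxidative phosphorylation were lower in astrocytes (41 of 58 members, median −0.20, camera adjusted p = 0.00241), striatal-type neurons (43 of 58, −0.13, 0.00717), excitatory neurons (46 of 58, −0.10, 0.0206) and fibroblasts (12 of 15, −0.22, 0.0367), with adjusted p = 0.345, 0.648, 0.684 and 0.463 with an estimated correlation. Glycolysis genes were lower in astrocytes (18 of 20, −0.23, camera adjusted p = 0.00347) and excitatory neurons (16 of 19, −0.18, 0.00490), with adjusted p = 0.258 and 0.684 with an estimated correlation. Cytoplasmic RNA genes were lower beside them in astrocytes, striatal-type neurons and fibroblasts (medians −0.24, −0.29 and −0.20), with a median of −0.14 in excitatory neurons that did not pass. Pfkfb3, an activator of glycolysis, fell by 0.82 ± 0.16 in excitatory neurons. Smaller shifts in excitatory neurons were those of clathrin endocytosis (28 of 38 lower, −0.06, camera adjusted p = 0.0415) and of the circadian clock (15 of 17 lower, −0.10, 0.0376), whose member Bhlhe41 fell by 0.64 ± 0.16. Both gave adjusted p = 0.684 with an estimated correlation. Glutamate receptor genes were higher in inhibitory (19 of 23, 0.14, camera adjusted p = 0.0104) and striatal-type neurons (19 of 22, 0.15, 0.00717), and GABA receptor and synthesis genes in striatal-type neurons (16 of 21, 0.11, 0.00717), with adjusted p = 0.744, 0.648 and 0.474 with an estimated correlation. Beside these lists inhibitory neuron markers were higher in striatal-type neurons (median 0.21), astrocyte markers there and in excitatory neurons (0.26 in each) and homeostatic astrocyte genes in inhibitory neurons (0.17). In excitatory neurons the presynaptic and postsynaptic lists did not pass over all lists (17 of 47 and 18 of 40 members higher, camera adjusted p = 0.0913 and 0.0613). Adjusted over the list alone 3 presynaptic members were higher and 10 lower, and 2 postsynaptic members higher and 13 lower. Pfkfb3 lost its call without any library but E3_2-3m_r4, E4_2-3m_r1 or r2, and Bhlhe41 without any 1 library, with the GC trend removed or with like shares of excitatory clusters (edgeR adjusted p up to 0.149). Glycolysis genes in both classes, oxidative phosphorylation genes in astrocytes and GABA genes kept their calls with any 1 library left out. The oxidative phosphorylation call was lost in excitatory neurons without E3_2-3m_r4, E4_2-3m_r1 or r3, in striatal-type neurons without these or E3_2-3m_r2 and in fibroblasts without any library but E3_2-3m_r1 or E4_2-3m_r3 (camera adjusted p up to 0.752). The clathrin call was lost without E3_2-3m_r3, E4_2-3m_r2 or r4 and the clock call without E3_2-3m_r4, E4_2-3m_r2 or r4. Glutamate receptor genes lost theirs in striatal-type neurons without E3_2-3m_r4 or E4_2-3m_r3 and in inhibitory neurons without these or E3_2-3m_r2 (up to 0.245 for these lists).

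Markers of other cell types moved within neurons. In excitatory neurons of younger E4 mice, astrocyte markers were higher (21 of 29, median 0.26, camera adjusted p = 0.00956) and so were genes of homeostatic astrocytes and their endfeet (21 of 27, 0.16, 0.00490), both with adjusted p = 0.684 with an estimated correlation. Hepacam and Slc4a4, an adhesion protein and a bicarbonate transporter of astrocytes, rose by 0.78 ± 0.15 and 0.61 ± 0.13. Beside them Gpc4 rose by 0.54 ± 0.11 and Prex2 by 0.48 ± 0.11, while Phkg1 fell by 0.47 ± 0.11. Slc1a3, the abundant glutamate transporter of astrocytes, was at 4.61 ± 0.453 and 6.98 ± 0.889 CPM without passing (0.67 ± 0.18, edgeR adjusted p = 0.0537). The homeostatic astrocyte list was higher in inhibitory neurons (15 of 23, 0.17, camera adjusted p = 0.0384), and astrocyte and inhibitory neuron markers in striatal-type neurons (16 of 21, 0.26, 0.00717, and 16 of 25, 0.21, 0.00717), with adjusted p = 0.632, 0.599 and 0.648 with an estimated correlation. Cytoplasmic RNA genes were lower in these striatal-type neurons (median −0.29). The 5 single genes that passed lost their calls without any 1 library but E3_2-3m_r4 or E4_2-3m_r2. With the GC trend removed Prex2 and Phkg1 lost theirs, as did Prex2 with as many excitatory nuclei per library and Phkg1 with like shares of excitatory clusters (edgeR adjusted p up to 0.143). Of the lists 2 lost their calls, namely the homeostatic list in inhibitory neurons without E3_2-3m_r1, r2, E4_2-3m_r1 or r3 (camera adjusted p up to 0.136) and inhibitory neuron markers without E4_2-3m_r2 (0.0698).

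At 9–12 months few single genes differed between E4 and E3 mice, and none of them was among those called at 2–3 months. In excitatory neurons Frrs1 (ENSMUSG00000033386, a ferric reductase; chromosome 3, 116859464 to 116908177, plus strand) rose from 0.425 ± 0.196 to 3.61 ± 0.658 CPM (SD, n = 3 and 5), a log2 fold of 3.1 ± 0.29 (SE; edgeR adjusted p = 6.92e-05). In pericytes Ntn1, the guidance cue netrin 1 (chromosome 11, 68209364 to 68400823), fell by 1.11 ± 0.23 on the log2 scale, from 567 ± 74.2 to 249 ± 58.7 CPM (edgeR adjusted p = 0.0216). In astrocytes the kinase gene Map3k19 fell by 1.06 ± 0.18, from 90.0 ± 36.4 to 41.2 ± 7.73 (edgeR adjusted p = 0.0300). D10Wsu102e (chromosome 10, 83360221 to 83488505) rose by 1.76 ± 0.31 in astrocytes, 1.58 ± 0.27 in oligodendrocyte precursors, 1.89 ± 0.28 in inhibitory and 2.16 ± 0.35 in striatal-type neurons (edgeR adjusted p from 0.0160 to 0.0325). Aldh1l2, a folate enzyme of mitochondria, rose by 2.29 ± 0.38 in striatal-type neurons, but its annotation overlaps the end of D10Wsu102e, so their counts are uncertain. The predicted gene Gm42743 was higher in astrocytes, inhibitory and striatal-type neurons. So was Tpm3-rs7, a near-identical copy of Tpm3 and thus uncertain, in inhibitory neurons. Of the 424 genes called in excitatory neurons at 2–3 months, 321 had the same direction at 9–12 months, 85 of them with an unadjusted p under 0.05.

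At 9–12 months only Frrs1 and, in striatal-type neurons, Gm42743 kept their calls with any 1 library left out. E3_9-12m_r3 stood apart from r1 and r2 of its group, with a chi-square per degree of freedom of 75.3 and 79.2 against 15.03 between these. E4_9-12m_r2 and r4 gave 11.6 and other older E4 pairs 34.1 to 68.7. Both close pairs were low in Xist and the other older libraries high, a split uneven by genotype. Left out in turn, E3_9-12m_r3 lay nearer its own group for 11% of the 100 genes of smallest p in excitatory neurons. Without E3_9-12m_r3 the count went from 3 to 104 in astrocytes, from 1 to 29 in excitatory neurons, from 1 to 17 in oligodendrocyte precursors, from 3 to 6 in inhibitory and 3 to 7 in striatal-type neurons and from 1 to 2 in pericytes. The excitatory count was 6 without E4_9-12m_r2, 3 without E4_9-12m_r1 and 2 without E3_9-12m_r1 or E4_9-12m_r5. The astrocyte count was 0 without E4_9-12m_r2 or E3_9-12m_r2 and 1 without E3_9-12m_r1 or E4_9-12m_r5, and Map3k19 lost its call without these libraries or E4_9-12m_r3. Ntn1 lost its call without any 1 E3 library or E4_9-12m_r4 (edgeR adjusted p from 0.0547 to 0.196). The precursor and inhibitory counts were 0 without E3_9-12m_r2 or E4_9-12m_r5 and the latter 1 without E3_9-12m_r1. The striatal-type count was 1 without E4_9-12m_r1 or E3_9-12m_r2 and 5 without E4_9-12m_r3 or r5. D10Wsu102e lost its call in each class without E3_9-12m_r2, in all but inhibitory neurons without E4_9-12m_r1, in all but striatal-type neurons without E4_9-12m_r5 and in astrocytes without E4_9-12m_r2 or r3. Gm42743 lost it in astrocytes without E3_9-12m_r1, r2 or E4_9-12m_r2 and in inhibitory neurons without E3_9-12m_r1, r2, E4_9-12m_r1 or r5. Tpm3-rs7 lost it without any but E3_9-12m_r3, E4_9-12m_r1 or r3, and Aldh1l2 without any but E4_9-12m_r2, r3 or r5 (edgeR adjusted p up to 0.988). Fitted on the older libraries alone, Ntn1, Map3k19, Aldh1l2 and D10Wsu102e lost their calls in each class named for them, and Gm42743 in astrocytes. Map3k19 and D10Wsu102e in astrocytes also lost theirs with Xist as a covariate (edgeR adjusted p = 0.0600 each), Ntn1 with no low-count filter (0.794), D10Wsu102e in inhibitory neurons with at most 50 nuclei per library (0.105) and Aldh1l2 with no doublet removal (0.112) or DESeq2 (0.0874).

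In the vascular classes and microglia at 9–12 months, no gene of the barrier passed. Cldn5 was at 951 ± 372 and 1116 ± 312 CPM in E3 and E4 endothelial nuclei (log2 fold 0.28 ± 0.26, edgeR adjusted p = 0.999) and Slc2a1 at 2179 ± 952 and 2252 ± 357 (0.10 ± 0.24, edgeR adjusted p = 0.999). Pdgfrb was at 1337 ± 65.9 and 1284 ± 91.6 in pericytes (−0.04 ± 0.19, edgeR adjusted p = 0.996). The smallest p belonged to Slc16a9, a carrier of carnitine, in endothelial nuclei (1.01 ± 0.22, edgeR adjusted p = 0.236) and to Macrod2 in microglia (0.98 ± 0.21, edgeR adjusted p = 0.366), and neither was called. By edgeR 0 genes were called in endothelial nuclei, fibroblasts, microglia and oligodendrocytes, with 161, 190, 352 and 417 at an unadjusted p under 0.05 and 0 by DESeq2 in each. Endothelial nuclei and microglia gave 2 calls each without E3_9-12m_r3, microglia 1 without E4_9-12m_r5, and oligodendrocytes 21 and 1 without E3_9-12m_r3 and r1. Of simulated changes at this age, 36 of 67 genes at 2-fold and 60 of 66 at 4-fold were found in endothelial nuclei, and 39 and 53 in pericytes.

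Among the lists, immediate early genes were lower in all 3 neuronal classes of the older E4 mice. The median was −0.75 in excitatory neurons with 28 of 30 members lower (camera adjusted p = 6.54e-11), −0.54 in inhibitory neurons with 23 of 27 (3.82e-07) and −0.36 in striatal-type neurons with 24 of 26 (0.00529). With an estimated correlation these gave adjusted p = 0.814, 0.882 and 0.979. None was called over all genes. Adjusted over the list alone 8, 4 and 3 members were lower, with Nr4a1 and Nr4a3, activity-induced nuclear receptors, at −0.63 ± 0.18 and −1.59 ± 0.47 in excitatory neurons. Cholesterol synthesis genes were lower in excitatory neurons (23 of 24, −0.38, camera adjusted p = 2.17e-10), inhibitory neurons (21 of 24, −0.27, 1.58e-06) and astrocytes (22 of 24, −0.33, 0.000335), with adjusted p = 0.814, 0.844 and 0.725 with an estimated correlation and 13 members in excitatory neurons and 4 in astrocytes adjusted over the list alone. Among them Idi1 and Cyp51, enzymes of isoprenoid and sterol synthesis, were at −1.19 ± 0.32 and −0.96 ± 0.27 in astrocytes, and Pmvk and Sqle at −0.49 ± 0.11 and −0.62 ± 0.19 in excitatory neurons. Heat shock and unfolded protein genes were lower in excitatory (27 of 29, −0.18, camera adjusted p = 0.000443) and inhibitory neurons (21 of 28, −0.12, 0.00616), with adjusted p = 0.814 and 0.882 with an estimated correlation. Excitatory neurons also had lower clathrin endocytosis (28 of 38, −0.08, camera adjusted p = 0.0220), cyclophilin A, NF-kappaB and MMP9 (10 of 12, −0.15, 0.0220) and circadian clock genes (13 of 17, −0.11, 0.0162), each with adjusted p = 0.814 with an estimated correlation. Cytoplasmic RNA genes were lower beside these in excitatory neurons (20 of 24, −0.17, camera adjusted p = 0.0220), astrocytes (23 of 23, −0.18, 0.000335) and pericytes (11 of 14, −0.40, 0.0271), with adjusted p = 0.894, 0.725 and 0.734 with an estimated correlation. Astrocyte markers were higher in the same excitatory and striatal-type neurons (medians 0.17 and 0.19) and excitatory neuron markers in the astrocytes (0.10).

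With 1 older library left out, only the immediate early and cholesterol lists in excitatory neurons kept their calls throughout among the 28 that passed. The immediate early list lost its call in inhibitory neurons without E3_9-12m_r1 and in striatal-type neurons without E3_9-12m_r1, r2, E4_9-12m_r3 or r5 (camera adjusted p up to 0.603). The cholesterol list lost it in inhibitory neurons without E3_9-12m_r1 and in astrocytes without E3_9-12m_r1 or r2 (up to 0.840), and the heat shock list in excitatory neurons without E3_9-12m_r2 and in inhibitory neurons without E3_9-12m_r1, r2 or E4_9-12m_r5 (up to 0.479). In excitatory neurons the clock call was lost without E3_9-12m_r1 or r2, the cyclophilin A call without E3_9-12m_r1 or E4_9-12m_r5 and the clathrin call without any library but E4_9-12m_r1 or r2 (up to 0.462). Cytoplasmic RNA genes lost theirs in astrocytes without E3_9-12m_r1, in pericytes without E3_9-12m_r1 or r2 and in excitatory neurons without these, E4_9-12m_r4 or r5 (up to 0.828).

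Endothelial nuclei of older E4 mice had higher interferon response genes (19 of 20 members, median 0.34, camera adjusted p = 0.000626, and adjusted p = 0.679 with an estimated correlation). Of these Rnf213, a ubiquitin ligase tied to moyamoya vessel disease, was at 0.50 ± 0.22 and Usp18, which restrains interferon signalling, at 0.90 ± 0.42. None was called over all genes or adjusted over the list alone. Pericyte markers were lower in endothelial nuclei (16 of 21, −0.21, camera adjusted p = 0.000348, and adjusted p = 0.727 with an estimated correlation), with the contractile protein gene Cald1 at −0.47 and the proteoglycan Cspg4 at −0.64. Fibroblasts had lower basement membrane and matrix genes (16 of 22, −0.23, camera adjusted p = 0.0396, and adjusted p = 0.263 with an estimated correlation), with the collagen-binding integrin Itga1 at −0.85 ± 0.24. Excitatory neuron markers were higher in pericytes (8 of 8, 0.45, camera adjusted p = 0.0271), oligodendrocytes (20 of 27, 0.18, 0.0380) and astrocytes (23 of 30, 0.10, 0.0277), with adjusted p = 0.368, 0.919 and 0.725 with an estimated correlation. Ion channel genes were higher beside them in oligodendrocytes (30 of 36, 0.15, camera adjusted p = 0.00229) and astrocytes (29 of 38, 0.14, 0.0244), and presynaptic genes in fibroblasts (16 of 21, 0.24, 0.0191), with adjusted p = 0.919, 0.740 and 0.273 with an estimated correlation. Layer 2 to 4 genes were higher in astrocytes (8 of 8, 0.30, camera adjusted p = 0.0382) and excitatory neurons (10 of 11, 0.15, 0.0107), and glutamate receptor genes in inhibitory neurons (20 of 23, 0.10, 0.0111), with adjusted p = 0.725, 0.814 and 0.882 with an estimated correlation. Astrocyte markers were higher in excitatory (24 of 29, 0.17, camera adjusted p = 0.0175) and striatal-type neurons (19 of 21, 0.19, 0.00851), with adjusted p = 0.814 and 0.979 with an estimated correlation. Cytoplasmic RNA genes were lower in the same pericytes, astrocytes and excitatory neurons (medians −0.40, −0.18 and −0.17). The interferon call was lost without E3_9-12m_r3 (camera adjusted p = 0.0906), that of pericyte markers without E3_9-12m_r2 (0.132) and that of matrix genes without any library but E4_9-12m_r5 (up to 0.134). Excitatory neuron markers lost their call in pericytes without E3_9-12m_r1, r2 or E4_9-12m_r1, in oligodendrocytes without any library but E3_9-12m_r3 or E4_9-12m_r4 and in astrocytes without any but E4_9-12m_r4 (up to 0.927). Ion channel genes in oligodendrocytes and presynaptic genes in fibroblasts lost theirs without E3_9-12m_r1, r2 or E4_9-12m_r1, and ion channel genes in astrocytes without these, E4_9-12m_r2 or r3 (up to 0.837). The layer list lost it in excitatory neurons without E3_9-12m_r2 and in astrocytes without any library but E4_9-12m_r1 or r4, and glutamate receptor genes without E3_9-12m_r1, r2, E4_9-12m_r1 or r5 (up to 0.612). Astrocyte markers lost it in excitatory neurons without E3_9-12m_r2 or E4_9-12m_r3 and in striatal-type neurons without these or E3_9-12m_r1 (up to 0.476).

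**Figure D3:**
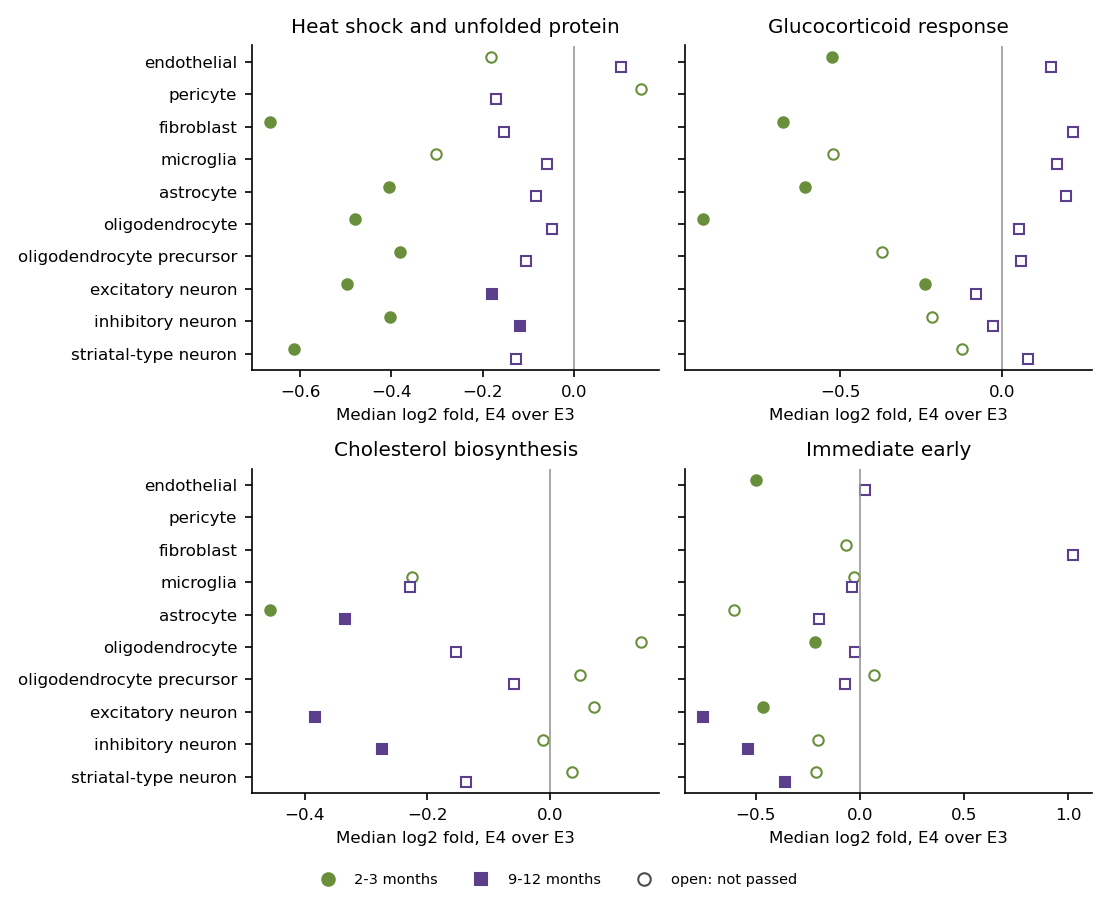
Median log2 fold of E4 over E3 (horizontal axis) for heat shock and unfolded protein, glucocorticoid response, cholesterol synthesis and immediate early genes in each cell class (vertical axis); circles are 2–3 months and squares 9–12 months, filled where the list passed with a preset correlation and open where it did not, with no point where under 3 members were tested. The heat shock median is −0.50 in excitatory neurons at 2–3 months and −0.18 at 9–12 months, and no list passed with an estimated correlation.

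Lists named for the vessel wall did not pass in endothelial nuclei at either age. Tight and adherens junction genes had medians of −0.01 and 0.05 (9 and 12 of 18 members higher, camera adjusted p = 0.948 and 0.321 at 2–3 and 9–12 months), barrier transporters −0.01 and 0.10 (11 and 20 of 25 higher, 0.948 and 0.118) and genes of caveolae −0.14 and −0.12 (2 of 9 higher at both ages, 0.628 and 0.594). Actin and contractility genes had medians of −0.01 and −0.06 (camera adjusted p = 0.948 and 0.212) and basement membrane genes −0.09 and −0.10 (0.749 and 0.208). In pericytes all 4 tested genes of the cyclophilin A, NF-kappaB and MMP9 list were lower at 9–12 months, with a median of −0.37 that did not pass (camera adjusted p = 0.0980). In microglia disease-associated genes had medians of 0.16 and −0.16 (camera adjusted p = 0.543 and 0.643) and homeostatic genes 0.09 and 0.06 (0.606 and 0.541). Sex-linked genes gave no call in any class, with camera adjusted p from 0.594 to 0.997 over classes and ages.

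The E4 effects of both ages were then compared directly in excitatory neurons, where 6 genes differed. Run codes and depth differed with age, so such differences, those of lists included, cannot be told from batch or depth. Angpt1 and Epha3 were higher in E4 than in E3 mice at 2–3 months and not at 9–12 months, with older means of 29.0 and 26.5 CPM for Angpt1 and 118 and 104 for Epha3 in E3 and E4 mice. The difference of the log2 folds was −1.13 ± 0.17 for Angpt1 and −0.69 ± 0.10 for Epha3 (SE; edgeR adjusted p = 0.0167 each). Frrs1 had the opposite order, with a difference of 2.72 ± 0.42 (edgeR adjusted p = 0.0192). Adam2, a membrane metalloprotease-like protein known from sperm, averaged 54.2 and 37.0 CPM in younger and 9.29 and 15.2 in older E3 and E4 mice (1.23 ± 0.18, edgeR adjusted p = 0.0167), and Fam196b 1.13 and 2.39 against 1.49 and 0.821 (−1.97 ± 0.29, 0.0167). The predicted gene Gm26615, outside the rule for names and given because the count is small, differed by 1.16 ± 0.19 (edgeR adjusted p = 0.0318). DESeq2 called 59 genes. The 6 calls became 0 without E3_2-3m_r1, r2 or E4_2-3m_r3, 1 without E4_2-3m_r4 or E3_9-12m_r2, and 16 without E3_9-12m_r3. Without E3_9-12m_r1, Angpt1, Epha3, Frrs1 and Gm26615 lost their calls, and Frrs1 also without E3_2-3m_r3 or r4. With 1 library left out Gm26615 kept its call only without E3_2-3m_r3, E4_2-3m_r1 or E3_9-12m_r3 and lost it with no low-count filter (edgeR adjusted p = 0.0513). In the other 9 classes edgeR called 0 genes, with 74 (pericytes) to 626 (striatal-type neurons) at an unadjusted p under 0.05 and 2 by DESeq2 in endothelial nuclei and oligodendrocytes and 0 in the rest. Without E3_9-12m_r3 there were 14, 8 and 2 in astrocytes, oligodendrocytes and oligodendrocyte precursors. There was 1 in fibroblasts without E3_2-3m_r4, in astrocytes without E4_2-3m_r2 and in inhibitory and striatal-type neurons without E3_9-12m_r1.

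Of the lists, glucocorticoid genes differed between the ages in oligodendrocytes (median difference of log2 folds 1.06, camera adjusted p = 5.06e-07), endothelial nuclei (1.04, 0.000715), fibroblasts (0.89, 0.00253) and astrocytes (0.49, 0.00165), being lower in younger E4 mice. Heat shock and unfolded protein genes differed in the same way in oligodendrocytes (0.50, camera adjusted p = 5.06e-07), striatal-type neurons (0.40, 2.97e-07), fibroblasts (0.53, 0.0282), astrocytes (0.28, 0.00492), excitatory (0.26, 0.000709) and inhibitory neurons (0.16, 0.0108), and glycolysis genes in astrocytes (0.29, 0.0144). Cholesterol synthesis genes differed the other way in excitatory (−0.40, camera adjusted p = 8.19e-06) and inhibitory neurons (−0.33, 0.000819), where they were lower at 9–12 months. None of the 13 passed with an estimated correlation (adjusted p = 0.628 to 0.999), a test added after the others were seen. Single libraries were not left out here.

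The older and the younger libraries differed in many genes in most classes, where age and batch cannot be told apart either. In endothelial nuclei Hdac9, a histone deacetylase, was higher in the older mice by 1.41 ± 0.14 on the log2 scale (edgeR adjusted p = 6.36e-07), and in pericytes the transcription factor Dach1 by 1.38 ± 0.24 (edgeR adjusted p = 0.000117). The neuronal noncoding RNA Bc1 was lower in non-neuronal classes, at −2.14 ± 0.22 in endothelial nuclei, −2.61 ± 0.21 in fibroblasts and −2.58 ± 0.16 in microglia. The calls numbered 11991 in excitatory neurons, 8294 in inhibitory and 7570 in striatal-type neurons, 4075 in astrocytes, 3603 in oligodendrocytes, 3274 in their precursors, 1465 in microglia, 890 in endothelial nuclei, 189 in fibroblasts and 59 in pericytes. Different clusters held the excitatory neurons of each age, with clusters 2, 5, 7, 13 and 19 almost all from younger and 4, 11, 12, 16 and 27 mostly from older mice. The pericyte calls were 26 higher and 33 lower by edgeR and 13 and 45 by DESeq2. They numbered 128 without E3_2-3m_r3, 107 without E3_2-3m_r1 or r2, 95 without E4_2-3m_r2 and 91 without E4_2-3m_r3. The fibroblast calls numbered 94 without E3_2-3m_r4 and 124 without E4_2-3m_r1.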

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

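The tests of astrocyte RNA, of mislabelled libraries, of cytoplasmic RNA and GC content for the heat shock genes, and the counts over other splits of the libraries were chosen after the results were seen, as were the rules that intervals or quartiles lie past a bound and the margins for library positions. By the rules as first written, on the value alone, cytoplasmic RNA (0.847) and astrocyte RNA (0.0576) would have been excluded and E4_9-12m_r1 (nearer E4 for 48% of genes), though it holds Loxl2, would have counted as mislabelled. A first test of a mislabelled library was dropped because it grouped libraries by a measured gene.

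Angpt1, Epha3, Cacng2 and Lrp1 were among 424 genes that differed in excitatory neurons of younger E4 mice, the higher ones low and the lower ones high in GC content. The tables argue against a GC trend as the whole cause, since with it removed the median signed log2 fold went from 0.565 to 0.494, or 0.874 of its size (95% interval over genes 0.849 to 0.911), and likewise against a trend with gene length (0.966 of its size, 0.930 to 0.992) and different shares of excitatory clusters (0.986, 0.962 to 1.01). With the GC trend removed 198 of the 424 stayed past the threshold, and in the 226 that did not the median size of the fold went from 0.51 to 0.41 and its median SE from 0.121 to 0.110, while the largest p that passed went from 0.00108 to 0.00054. Free RNA or nuclei of astrocytes stay open as a candidate source of part of the genes, because the 896 genes at least 4-fold higher in astrocytes had a median of 0.0576 with quartiles of −0.13 and 0.26. Of the 35 splits of the younger libraries 1, the real one, gave as many calls and the highest other gave 0. Taken alone this share is under 0.05, but it does not exclude chance. The count of splits was chosen after the calls were seen, and the 424 calls became 2 without E4_2-3m_r3. An effect of the genotype is a hypothesis.

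Loxl2 was near 0 in E3 mice and present in 6 classes of younger E4 mice, though not called in microglia with DESeq2 or the stricter nuclei filter. It was near 0 in 2 of the 5 older E4 libraries. A candidate explanation is a stretch of the genome that differs between the lines apart from APOE. It stays open, because of the 100 genes of smallest p in excitatory neurons 19 pairs lay within 1 Mb at 9–12 months, where the 95th percentile of random lists was 12, but 10 at 2–3 months and also 19 between ages. A wrong label as the reason for the missing Loxl2 stays open, for although E4_9-12m_r3 and E4_9-12m_r5, which lack it, held 4.52 and 3.86 CPM of Frrs1 and 65.0 and 75.7 of D10Wsu102e in excitatory neurons, against 0.26 to 0.64 and 8.55 to 36.0 in older E3 libraries, and lay nearer the other E4 libraries for 81% and 73% of genes, each did so for 62.5% of the 8 genes called off chromosome 14 in a fit without both (exact 95% interval 24.5% to 91.5%), and E3_9-12m_r3 lay nearer its own group for only 11%.

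Heat shock and unfolded protein genes, such as Pdia3, were lower in 7 classes of younger E4 mice at a preset correlation and in none with an estimated correlation (adjusted p = 0.116 to 0.913). The tables argue against a GC trend as the whole cause, since with it removed Hspa5 and Xbp1 lost their calls but the median in excitatory neurons kept 0.911 of its size (95% interval over members 0.857 to 1.20). Less cytoplasmic RNA stays open as part of the cause, since with that list as a covariate the median went from −0.50 to −0.42, or 0.847 of its size (0.750 to 1.01). Of the 35 splits of the younger libraries 1, the real one, gave this list in 7 classes and the highest other in 6, but the list was picked out after its result was seen, and 6 of 35 splits, the real one included, gave some list in 7 or more classes in the same direction, with 10 in the highest other, so chance cannot be excluded. An effect of the genotype is a hypothesis, and differences in how or when the tissue was collected were not tested.

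The counts of splits are not adjusted for their number. Taken alone, the share of splits as large was under 0.05 in oligodendrocytes and their precursors at 2–3 months. Each had 1 of 35 splits, with 6 and 2 calls real and 0 and 1 in the highest other. Neither excludes chance, since the counts were chosen after the calls were seen and both sets of calls became 0 without some single libraries. Chance cannot be excluded for pericytes and microglia (2 of 35 splits each, 1 call real and 1 in the highest other), inhibitory neurons (3 splits, 2 real, highest other 138) or striatal-type neurons (2 splits, 8 real, highest other 18). The split with 138 calls parts younger libraries high and low in Xist. They also differed in inhibitory cluster 28, at 0% to 0.184% and 2.11% to 4.47% of nuclei. At 9–12 months chance cannot be excluded in pericytes (16 of 56 splits, 1 call real, highest other 5), astrocytes (8 splits, 3 real, 381), oligodendrocyte precursors (16 splits, 1 real, 445), excitatory neurons (13 splits, 1 real, 2106), inhibitory neurons (3 splits, 3 real, 305) or striatal-type neurons (7 splits, 3 real, 753). The splits with 305 to 2106 calls point to a structure of the older libraries other than the genotype. Chance cannot be excluded for the number of passing lists either, at 35 lists real and 45 in the highest other at 2–3 months (5 of 35 splits as large) and 28 and 94 at 9–12 months (42 of 56). For the difference between ages in excitatory neurons 2 of 60 splits, a part of those possible, gave as many calls as the real 6. The highest other gave 12. This count does not exclude chance, and the 6 became 0 or 1 without some single libraries.

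Between ages 1 of 30 splits, the real one, gave as many calls in each class. The 30 are a part of those possible. The count argues against chance, though not against the batch. The highest other split called 16 genes in endothelial nuclei, 7 in pericytes, 13 in fibroblasts, 298 in microglia, 775 in astrocytes, 1182 in oligodendrocytes and 684 in their precursors. It called 6474 in excitatory, 4265 in inhibitory and 3367 in striatal-type neurons.

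The test of the difference between ages, which cannot be told from batch, passed for 6 genes in excitatory neurons. The log2 differences of the E4 effects were 1.23 for Adam2, −1.97 for Fam196b, −1.13 for Angpt1, −0.69 for Epha3, 2.72 for Frrs1 and 1.16 for Gm26615. At a preset correlation it passed for glucocorticoid genes, with median differences of 1.04 in endothelial nuclei, 0.89 in fibroblasts, 0.49 in astrocytes and 1.06 in oligodendrocytes. It passed for heat shock and unfolded protein genes, with medians of 0.53 in fibroblasts, 0.28 in astrocytes, 0.50 in oligodendrocytes, and 0.26, 0.16 and 0.40 in excitatory, inhibitory and striatal-type neurons. It also passed for glycolysis genes in astrocytes (0.29) and cholesterol synthesis genes in excitatory (−0.40) and inhibitory neurons (−0.33), and with an estimated correlation for none of these 13 lists.

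A single library lay far from the others of its group by Dixon's ratio in 12 of 196 tests, where chance gives about 1 in 20. E4_2-3m_r4 had 7.67% of nuclei in no tested class against 10.35% to 10.58%, and Calr, a chaperone, at 65.1 CPM in oligodendrocyte precursors against 46.0 to 47.3. E4_2-3m_r1 had Loxl2 at 93.1 in excitatory neurons against 41.0 to 44.1, and at 108 in striatal-type neurons against 43.8 to 53.6. E3_2-3m_r4 had Loxl2 at 3.32 in oligodendrocytes and 1.36 in their precursors, where the other younger E3 libraries had 0, and Prex2 at 18.2 in excitatory neurons against 14.8 to 15.2. Gpc4 was at 16.8 in excitatory neurons of E4_2-3m_r3 against 13.2 to 13.6, Asna1 at 5.28 in striatal-type neurons of E3_2-3m_r1 against 7.65 to 8.002, and Zbtb16 at 14.6 in astrocytes of E4_2-3m_r2 against 54.5 to 61.5. In the older mice APOE was at 1180 in astrocytes of E4_9-12m_r1 against 790.3 to 861, and Gm42743 at 9.57 in striatal-type neurons of E4_9-12m_r2 against 5.85 to 6.59.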

How the results depend on the processing

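The alternatives given with the processing as added later were chosen after the results were seen. Of 685 alternative counts of called genes 516 stayed within 1.5 times of the reported count and 169 did not. Of 240 alternative shares 212 kept their direction and 28 reversed, none of them called. Of 1592 alternative values of named genes 1211 kept direction and call, 345 lost the call, 17 gained it and 19 reversed, and no called gene reversed. Of 504 tests of 63 passing lists with 1 library of that age left out 361 kept and 143 lost the call, and 15 of 35 lists at 2–3 months and 2 of 28 at 9–12 months passed without any 1 library. The cause of each change below was not tested, except that at most 50 nuclei per library leaves fewer counts. No paired analysis was possible because no replicate number or label pairs mice of different groups. The stricter nuclei filter gave no count of called genes and no log2 fold for endothelial nuclei and pericytes at 2–3 months. Depth limits what could be found in the vascular classes.

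With DESeq2 the genes called at 2–3 months numbered 2 in endothelial nuclei, 0 in microglia, 6 in astrocytes, 22 in oligodendrocytes, 6 in oligodendrocyte precursors, 1089 in excitatory, 6 in inhibitory and 42 in striatal-type neurons. DESeq2 called at 9–12 months 5 in astrocytes, 3 in oligodendrocyte precursors, 26 in excitatory, 7 in inhibitory and 5 in striatal-type neurons. For the E4 effect at 9–12 against 2–3 months DESeq2 called 2 in endothelial nuclei, 2 in oligodendrocytes and 59 in excitatory neurons.

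With no low-count filter the genes called at 2–3 months were 14 in endothelial nuclei, 0 in pericytes, 13 in fibroblasts, 15 in microglia, 58 in astrocytes, 125 in oligodendrocytes, 48 in oligodendrocyte precursors and 46 in striatal-type neurons. Without that filter at 9–12 months they were 18 in endothelial nuclei, 31 in fibroblasts, 13 in microglia, 40 in astrocytes, 34 in oligodendrocytes, 18 in oligodendrocyte precursors, 9 in excitatory and 9 in striatal-type neurons. For the difference between the effects they were 10 in endothelial nuclei, 6 in fibroblasts, 2 in microglia, 25 in astrocytes, 48 in oligodendrocytes and 24 in oligodendrocyte precursors, and between ages 618 in pericytes and 369 in fibroblasts. The log2 fold of Pdgfrb in pericytes at 9–12 months was then 0.10.

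With only libraries of that age the genes called at 2–3 months were 0 in pericytes, 10 in microglia, 22 in astrocytes, 59 in oligodendrocytes, 25 in oligodendrocyte precursors, 1237 in excitatory and 45 in striatal-type neurons, and at 9–12 months 0 in pericytes, astrocytes and oligodendrocyte precursors, 2 in excitatory and 1 in striatal-type neurons. Gene lists passing with only libraries of that age were 2 in fibroblasts at 2–3 months and at 9–12 months 0 in pericytes and fibroblasts, 3 in astrocytes and 4 in oligodendrocytes. With an estimated correlation 0 lists passed at 2–3 and 9–12 months in each class with lists that passed at the preset one.

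With Xist as a covariate the genes called at 2–3 months were 0 in pericytes, 2 in microglia, 6 in oligodendrocyte precursors, 1051 in excitatory and 24 in striatal-type neurons, and at 9–12 months 1 in astrocytes and 5 in striatal-type neurons. With at most 50 nuclei per library they were 0 at 2–3 months in pericytes, microglia, oligodendrocytes, oligodendrocyte precursors, inhibitory and striatal-type neurons and 3 in excitatory neurons, and at 9–12 months 0 in astrocytes, oligodendrocyte precursors and excitatory neurons and 1 in inhibitory and in striatal-type neurons, and the log2 fold of APOE in microglia at 2–3 months was −0.16. With no doublet removal 0 genes were called in pericytes and inhibitory neurons at 2–3 months, the share difference, E4 minus E3, was 0.0094 percentage points in fibroblasts at 9–12 months and −0.049 in striatal-type neurons at 2–3 months, and the log2 fold at 2–3 months was −0.05 for Pdgfrb in pericytes and −0.013 for Lrp1 in astrocytes. With the stricter nuclei filter 0 genes were called in microglia, 1 in oligodendrocytes and 4 in oligodendrocyte precursors at 2–3 months, the share difference was −0.0074 in endothelial nuclei and 0.098 in microglia at 2–3 months and −0.018 in endothelial nuclei and 0.012 in fibroblasts at 9–12 months, and the log2 fold of Slc2a1 in endothelial nuclei at 9–12 months was −0.19. Over all kept nuclei the log2 fold of APOE, reported in astrocytes, was 0.14 at 2–3 and 0.045 at 9–12 months. With the GC content trend removed 213 genes were called in excitatory neurons at 2–3 months, and at 9–12 months 7 with like shares of excitatory clusters and 4 with as many excitatory nuclei per library.

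With each library left out in turn, the called genes at 2–3 months ranged from 0 to 1 in pericytes, 0 to 3 in astrocytes, 0 to 6 in oligodendrocytes, 0 to 5 in oligodendrocyte precursors, 2 to 497 in excitatory, 0 to 2 in inhibitory and 0 to 6 in striatal-type neurons. The highest came without E4_2-3m_r2 in astrocytes, excitatory and inhibitory neurons, without E4_2-3m_r3 in oligodendrocytes and without E3_2-3m_r4 in precursors and striatal-type neurons. At 9–12 months they ranged from 0 to 2 in endothelial nuclei, pericytes and microglia, 0 to 104 in astrocytes, 0 to 21 in oligodendrocytes, 0 to 17 in oligodendrocyte precursors, 1 to 29 in excitatory, 0 to 6 in inhibitory and 1 to 7 in striatal-type neurons, each highest without E3_9-12m_r3. For the difference between the effects they ranged from 0 to 1 in fibroblasts (1 without E3_2-3m_r4), inhibitory and striatal-type neurons (1 without E3_9-12m_r1), and from 0 to 14 in astrocytes, 0 to 8 in oligodendrocytes, 0 to 2 in precursors and 0 to 16 in excitatory neurons, highest without E3_9-12m_r3. Between ages they ranged from 48 to 128 in pericytes (without E4_9-12m_r2 and E3_2-3m_r3) and from 94 to 230 in fibroblasts (without E3_2-3m_r4 and E4_9-12m_r4). Share differences that reversed ranged at 2–3 months from −0.038 to 0.091 in endothelial nuclei, −0.172 to 0.189 in microglia, −0.484 to 0.845 in inhibitory and −0.233 to 0.514 in striatal-type neurons, and at 9–12 months from −0.125 to 0.117 in fibroblasts, −0.086 to 1.80 in astrocytes and −0.520 to 0.363 in inhibitory neurons. The log2 fold of APOE at 2–3 months ranged from −0.16 to 0.24 in microglia and −0.34 to 0.058 in astrocytes, and at 9–12 months from −0.24 to 0.012 in astrocytes, and that of Lrp1 in astrocytes at 2–3 months from −0.082 to 0.080. At 9–12 months Pdgfrb in pericytes ranged from −0.084 to 0.0025, Cldn5 in endothelial nuclei from −0.00098 to 0.52 and Slc2a1 there from −0.17 to 0.52.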

Other observations

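The values below were picked out after they were seen.

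In microglia, interferon response genes had a median log2 fold of 0.24 at 2–3 months, with 6 of 7 members higher, and 0.13 at 9–12 months, and did not pass (camera adjusted p = 0.137 and 0.451). Complement genes had medians of −0.11 and 0.01 there (camera adjusted p = 0.606 and 0.4933). In astrocytes, genes of the reactive state had medians of −0.17 and 0.06 (camera adjusted p = 0.777 and 0.998) and genes of lipoprotein and lipid handling −0.04 and −0.05 (0.642 and 0.441). Myelin genes in oligodendrocytes had medians of 0.04 and −0.03 (camera adjusted p = 0.900 and 0.847). In excitatory neurons, autophagy and lysosome genes were at −0.06 and −0.08, with 23 and 22 of 32 members lower (camera adjusted p = 0.0913 and 0.0660), and genes beside Apoe in the genome at −0.18 and 0.01 (0.215 and 0.984).

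D10Wsu102e, called in 4 other classes of the older mice, was in excitatory neurons at 34.2 to 38.6 CPM in younger E3 and 55.5 to 66.6 in younger E4 libraries, without a call. In the older mice it was at 36.0, 9.01 and 8.55 in the 3 E3 libraries and 65.0 to 79.6 in the E4 libraries. APOE averaged 242.5 ± 32.0 and 241 ± 91.1 CPM in microglia of younger E3 and E4 mice and 220.4 ± 45.3 and 262.5 ± 74.98 in the older ones (SD, n = 4, 4, 3 and 5). Xist in excitatory neurons was at 1285.5 to 2265.6 CPM in 2 of 4 libraries of each younger group, 1 of the 3 older E3 and 3 of the 5 older E4 libraries, and at 0.40 to 0.85 in the others.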
